A study of Homo sapiens with 12 samples.

How the data were processed

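The series holds 12 RNA-seq libraries of the MDA-MB-231 breast cancer cell line, 3 wells each with no drug, 1 µM DEX, 8 µM SH4-54 or both for 24 h. Per the labels' protocols, total RNA was extracted, ribosomal RNA was removed and stranded libraries were sequenced as 50-base single-end reads. Groups and replicate numbers were taken from the sample titles. The treatment tag of the SH4-54 samples spells the compound SH5-54, and the titles and series design were followed. The vehicle of the no-drug wells is not given in the sources used here. The labels name replicate wells, so p-values measure the spread between wells.

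The authors deposited 1 table of whole-number read counts per gene symbol, 26364 rows for 12 libraries, of which 4474 were 0 in every library. The table was made with HISAT2 2.1.0, SAMtools and featureCounts 1.5.1, and the builds hg19 and GRCh37 are named, per the submitters' processing notes. The annotation, the strand setting of the counting and the handling of reads that map to several places are not given in the sources used here, so genes with near-identical copies and overlapping genes are uncertain. Of the symbols, 23795 matched a current symbol and 25261 a current or older one. The reference given was a different build, so no coordinates are printed. The mitochondrial-genome genes have no rows.

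Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered by edgeR's filterByExpr with the group as factor, leaving 14184, libraries were scaled by TMM, and 1 quasi-likelihood model (glmQLFit, glmQLFTest) with the 4 groups was fitted to all 12 libraries, with 8 residual degrees of freedom. The 6 comparisons were DEX, SH4-54 and both against no drug, both against DEX, both against SH4-54, and the interaction. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05, and every adjusted p given for a gene is edgeR's. Standard errors of log2 fold changes were derived from the test, as the absolute log2 fold change over the square root of its F statistic. Their median was 0.0636 for DEX and for SH4-54 against no drug and 0.09 for the interaction. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2.

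Genes named were chosen by a rule fixed before the data were examined: adjusted p below 0.05, a mean of at least 5 CPM in a group, no overlap between the log2 CPM of the groups compared, then the 10 largest rises and falls for DEX, SH4-54 and the interaction and 5 each for the other comparisons, with up to 4 members of each list by smallest p, and NR3C1, STAT3, STAT5A, STAT5B and FKBP5 always. Some items that the rule takes are not reported here. Other genes (CRISPLD2, INSIG1, GCLM, VIM and TNC with DEX, and those of the closing section's gene groups) were chosen after their values were seen. The 15 gene lists were also fixed beforehand from textbook knowledge: glucocorticoid-induced, NF-kB and AP-1 inflammatory, STAT3 target, interferon-stimulated, DNA replication and G1/S, G2/M and mitosis, ATF4 stress, ER chaperone, heat shock, NRF2 antioxidant, cholesterol synthesis, hypoxia and glycolysis, mesenchymal and matrix, mitochondrial-genome and luminal epithelial genes. They were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. List members counted as risen or fallen passed over all genes; counts adjusted over the list alone stand beside them where they differ. CEBPD, ANGPTL4, BIRC5, VEGFA, TWIST1, SLC7A11 and LOX each belong to a pair of lists.

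The tests were tried on simulated counts with 200 changed genes. For DEX against no drug the simulation recovered 33 of 50 genes changed 1.25-fold, 38 of 50 changed 1.5-fold, 43 of 50 changed 2-fold and 49 of 50 changed 4-fold, with 5.23% of calls on unchanged genes. For SH4-54 the numbers were 28, 35, 44 and 50 of 50, and for the interaction 13, 39, 38 and 46 of 50. A simulated response kept at 0.7 gave a ratio of 0.664 with genes chosen by DEX and 0.71 with genes chosen by both arms. With genes chosen by both compounds against SH4-54 the inverse ratio (effect without SH4-54 over effect with it), 1.43 in the simulation, came out as 1.33. The data gave 0.886 for that inverse ratio, on the other side of 1.

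Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no count filter, a stricter filter (at least 1 CPM in 3 libraries and a mean of 20 counts), the replicate number as a block, the compared groups alone, removal of the 10 most abundant genes, and leaving out each library. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom at least 4.18).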

Results

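RNA was sequenced from MDA-MB-231, a human triple-negative breast cancer cell line with mesenchymal features. Wells received no drug, 1 µM dexamethasone (DEX), a synthetic agonist of the glucocorticoid receptor, 8 µM SH4-54, a small-molecule inhibitor of STAT3 and STAT5, or both compounds, each for 24 h. Each of the 4 groups held 3 wells. Counted reads per library ranged from 28439725 to 31552360 without drug, from 26040956 to 29426776 with DEX, from 25577213 to 28864061 with SH4-54 and from 26280158 to 35758236 with both compounds. Of the 26364 gene rows, 14184 had enough counts to be tested. The first principal component of log2 CPM (read counts scaled to library size) held 50.3% of the variance and parted the wells with DEX from those without it. The second held 17.5% and parted the wells with SH4-54 from those without it. It ran from 15.9 to 17.9 with DEX, from 7.26 to 10.9 without drug and from -6.52 to -2.11 with SH4-54 alone. The combination wells lay farthest out, replicate 2 most of all (-31.4, against -22.3 and -13 for the other combination wells). Below, values after ± are SD over 3 wells for CPM and standard errors for log2 fold changes.

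The comparison of DEX with no drug asked what the glucocorticoid alone changed. The glucocorticoid target genes FKBP5 and TSC22D3 rose from 53.9 ± 1.6 to 326 ± 17.5 CPM and from 6.82 ± 0.499 to 85.9 ± 1.9 CPM. The cytokine gene IL11 fell from 230 ± 15.6 to 11.9 ± 0.395 CPM. NR3C1, which encodes the glucocorticoid receptor itself, fell from 494 ± 6.1 to 275 ± 2.9 CPM. In all, 3104 genes rose and 3293 fell (edgeR quasi-likelihood test, adjusted p below 0.05), of which 298 rose and 385 fell at least 2-fold.

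Genes close to the detection limit without DEX led the risen genes. ALOX15B, a lipoxygenase gene, went from 0.01 to 11.2 ± 1.5 CPM, IP6K3 from 0.021 to 10.8 ± 0.46 CPM and the dipeptidase gene DPEP1 from 0.023 to 5.59 ± 0.68 CPM. MAP2 rose from 0.471 ± 0.23 to 28.4 ± 0.52 CPM. SLC7A7, KCCAT211, ANGPTL4 and PLD5 had log2 fold changes of 4.71 ± 0.23, 4.12 ± 0.14, 3.99 ± 0.080 and 3.82 ± 0.16. Among the fallen genes, ASB2 had a log2 fold change of -5.28 ± 0.38, the tight-junction gene CLDN2 -4.40 ± 0.22, IL11 -4.27 ± 0.19 and the stem-cell marker gene LGR5 -4.25 ± 0.14. ANXA10 (-3.12 ± 0.17), LINC00704 (-3.00 ± 0.18), SPNS2 (-2.74 ± 0.11) and RELN (-2.71 ± 0.13) followed. HIST2H2BA and ZNF84 also met the rule for named genes and are uncertain, since their CPM varied widely between no-drug wells (59.2 ± 97.3 and 8.41 ± 3.2). Without no-drug replicate 2 the adjusted p of HIST2H2BA was 0.838, and without DEX replicate 1 that of ZNF84 was 0.093 (edgeR).

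Glucocorticoid-induced genes rose and mitotic genes fell. Of 24 tested glucocorticoid-induced genes, 22 rose and 1, CRISPLD2, fell, with the same counts when adjusted over the list alone (camera adjusted p = 2.65e-76). BIRC3, an inhibitor of apoptosis gene, and the metallothionein gene MT2A had log2 fold changes of 2.41 ± 0.045 and 2.46 ± 0.043. Of 25 G2/M and mitosis genes, 24 fell, also when adjusted over the list alone (camera adjusted p = 3.03e-22). The kinesin gene KIF20A went from 343 ± 3.9 to 173 ± 2.6 CPM and CENPE had a log2 fold change of -0.70 ± 0.033. Of 25 DNA replication and G1/S genes 12 fell and 1 rose, and the list did not pass (camera adjusted p = 0.113). Of 23 STAT3 target genes 14 rose and 7 fell (camera adjusted p = 0.000639). NNMT (2.87 ± 0.11), CEBPB (1.66 ± 0.074) and MYC (0.74 ± 0.034) rose and FOSL2 (-0.65 ± 0.038) fell. Of 18 mesenchymal and matrix genes 8 rose and 5 fell, or 8 and 7 when adjusted over the list alone. That list passed upward (camera adjusted p = 4.65e-11) with a mean log2 fold change of 0.473 and a median of -0.0805. The integrin gene ITGA5 (1.56 ± 0.067) and the transcription factor gene SNAI2 (1.29 ± 0.055) rose, while VIM (-0.64 ± 0.062) and TNC (-1.06 ± 0.087) fell. The 4 list calls in this paragraph also held with an estimated correlation between genes.

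Calls for 4 other lists were lost with an estimated correlation. Of 24 cholesterol synthesis and SREBP2 genes 21 rose and 0 fell (camera adjusted p = 2.19e-07, adjusted p = 0.211 with an estimated correlation), including DHCR7 (0.52 ± 0.053) and FDPS (0.35 ± 0.033). Of 19 ER chaperone genes 14 rose, led by HSPA5 at 0.45 ± 0.044 (camera adjusted p = 0.00532, adjusted p = 0.211 with an estimated correlation). Of 19 hypoxia and glycolysis genes 9 rose and 6 fell (camera adjusted p = 0.00532, adjusted p = 0.211 with an estimated correlation). Of 15 luminal epithelial markers 9 fell, including ELF3 (-2.07 ± 0.10) and CLDN4 (-1.14 ± 0.055), and 3 rose (camera adjusted p = 0.00307, adjusted p = 0.211 with an estimated correlation). The 21 NF-kB and AP-1 inflammatory genes went both ways, 7 up and 11 down (camera adjusted p = 0.528). The chemokine genes CXCL3 (2.22 ± 0.16) and CXCL2 (2.15 ± 0.17) rose, and the protease gene PLAU (-1.81 ± 0.11) fell. Of 24 interferon-stimulated genes 6 rose and 4 fell, or 2 without no-drug replicate 1 (camera adjusted p = 0.528). Of 25 ATF4 stress genes 5 rose and 13 fell, or 5 and 15 when adjusted over the list alone (camera adjusted p = 0.0907). Of 15 heat shock genes 2 rose and 5 fell (1 rose without no-drug replicate 2 and 4 when combination replicate 3 was left out of the shared fit), with a mean of 0.0786, a median of -0.102 and a test pointing down (camera adjusted p = 0.143). Of 20 NRF2 antioxidant genes 3 rose and 10 fell, or 4 and 11 when adjusted over the list alone (camera adjusted p = 0.289). The STAT3 transcript rose by 0.19 ± 0.040 on the log2 scale (edgeR adjusted p = 0.00101).

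SH4-54 alone, compared with no drug, changed fewer genes by the same test. HSPA6, an inducible heat shock gene, rose from 0.408 ± 0.13 to 24 ± 4.1 CPM. The immediate-early genes ARC, FOSB and FOS rose from 0.0989 ± 0.032 to 3.08 ± 0.33 CPM, from 0.238 ± 0.12 to 2.09 ± 0.37 CPM and from 1.73 ± 0.10 to 6.36 ± 1.4 CPM. The matrix metalloprotease gene MMP3 and the chemokine gene CCL26 rose to 1.77 ± 0.29 and 6.87 ± 0.64 CPM. In all, 38 genes rose, 8 of them at least 2-fold, and 47 fell by less than that. Next among the risen genes were ANGPTL4 (0.74 ± 0.095), FTH1 (0.62 ± 0.053), HMOX1 (0.61 ± 0.098) and the pseudogene GUSBP1 (0.60 ± 0.095). The largest falls among named genes were those of MPZL2 (-0.60 ± 0.11), RCSD1 (-0.57 ± 0.074), AGR2 (-0.53 ± 0.091) and CCNA1 (-0.47 ± 0.069). The transcripts of the compound's named targets did not pass. Their log2 fold changes were -0.03 ± 0.040 for STAT3 (edgeR adjusted p = 0.836), 0.02 ± 0.079 for STAT5A (0.96) and -0.07 ± 0.043 for STAT5B (0.55). The count of 85 changed with the library left out, and each such fit also has fewer wells. It was 55, 26 or 35 without no-drug replicate 1, 2 or 3, 48 or 47 without SH4-54 replicate 1 or 2, and 138 or 163 when combination replicate 2 or 3 was left out of the shared fit. It was 180 with DESeq2, 176 without a count filter and 155 with the libraries of both groups alone, and 1862 genes had an unadjusted p below 0.05. Of 31 named genes called, 15 kept the call whichever library was left out, and without no-drug replicate 2 the calls of FOS (edgeR adjusted p = 0.0507), CCL26 (0.0789), HMOX1 (0.0723) and CCNA1 (0.0501) were lost. That of AGR2 was lost without no-drug replicate 1 (0.0624), and that of MPZL2 in 5 of 12 left-out fits, with 0.0686, 0.0698 or 0.0905 without no-drug replicate 1, 2 or 3 and 0.102 or 0.0817 without SH4-54 replicate 1 or 2.

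With SH4-54 alone, of 20 NRF2 antioxidant genes 5 rose, or 14 when adjusted over the list alone (camera adjusted p = 2.27e-25): FTH1, HMOX1, NQO1 (0.45 ± 0.033), TXNRD1 (0.27 ± 0.041) and GCLM (0.23 ± 0.042). Without no-drug replicate 2 the number was 3. Of 21 NF-kB and AP-1 genes MMP3 rose (3 rose when adjusted over the list alone, camera adjusted p = 6.06e-07). Both calls held with an estimated correlation. Of 24 cholesterol synthesis genes 3 fell, ACAT2 (-0.18 ± 0.034) and MVK (-0.26 ± 0.055) among them, or 18 when adjusted over the list alone. The list passed downward (camera adjusted p = 2.18e-21, adjusted p = 0.0697 with an estimated correlation). Without no-drug replicate 1, 2 or 3 or SH4-54 replicate 1 or 2 none of its members passed by edgeR. Without SH4-54 replicate 3 the number that fell was 1, and it was 11 or 12 when combination replicate 2 or 3 was left out of the shared fit. Without no-drug replicate 3 the adjusted p of ACAT2 was 0.128 and without SH4-54 replicate 1 that of MVK was 0.174. Of 24 glucocorticoid-induced genes ANGPTL4, RGS2, MT2A and BIRC3 rose, and 1 fell when adjusted over the list alone (camera adjusted p = 2.57e-05, adjusted p = 0.0885 with an estimated correlation). Among interferon-stimulated genes ISG15 (-0.24 ± 0.040) fell, or 4 of 24 when adjusted over the list alone (camera adjusted p = 5.89e-06, adjusted p = 0.231 with an estimated correlation). Among mitotic genes KIF20A (-0.25 ± 0.044) fell, or 9 of 25 when adjusted over the list alone (camera adjusted p = 1.06e-06, adjusted p = 0.231 with an estimated correlation). Among luminal markers AGR2 and KRT19 (-0.20 ± 0.036) fell, or 6 of 15 when adjusted over the list alone (camera adjusted p = 5.89e-06, adjusted p = 0.0885 with an estimated correlation). Without no-drug replicate 2 the calls of ISG15 (edgeR adjusted p = 0.0518), KIF20A (0.0911), KRT19 (0.117) and BIRC3 (0.0852) were lost.

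The heat shock list had a median log2 fold change of 0.07 with SH4-54 (camera adjusted p = 0.0339, adjusted p = 0.408 with an estimated correlation). Of the STAT3 target genes FOS rose (camera adjusted p = 0.0615). Of the 18 mesenchymal genes 1 rose, or 2 when adjusted over the list alone. That list had a median of -0.0126 and a mean of 0.0204 and did not pass (camera adjusted p = 0.116). Of the hypoxia genes ANGPTL4 rose (median -0.00822, mean 0.0167, camera adjusted p = 0.297). The ER chaperone list (median -0.0315, camera adjusted p = 0.147, 3 fell when adjusted over the list alone), the ATF4 list (median -0.0451, 0.276) and the DNA replication list (median 0.0219, 0.296) did not pass.

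The comparison of both compounds with DEX alone asked what SH4-54 changed in DEX-treated cells. HSPA6 stood at 0.394 ± 0.22 CPM with DEX and at 150, 483 and 156 CPM in the 3 combination wells, and FOS rose from 1.19 ± 0.11 to 26.4 ± 10.1 CPM. ARC, FOSB and MMP3 stood at 16.6 ± 6.5, 9.35 ± 3.8 and 6.79 ± 1.7 CPM with both compounds and below 0.2 CPM with DEX. FAM166A went from 0.0498 ± 0.024 to 5 ± 2.4 CPM. All 24 tested cholesterol synthesis genes fell. In total 1851 genes rose and 1919 fell, 163 and 44 of them at least 2-fold. The largest falls among named genes were those of IP6K3 (-1.59 ± 0.28), ALOX15B (-1.29 ± 0.32), MAP2 (-1.22 ± 0.19) and the complement gene C3 (-1.15 ± 0.20), each of which DEX had raised. LINC01123 was also called lower but is uncertain, as its CPM varied between DEX wells (11.6 ± 13.7) and its adjusted p was 0.721 without DEX replicate 2. The number called was 2776, 2213 or 4633 without combination replicate 1, 2 or 3. It was 2957, 2663 or 2847 without DEX replicate 1, 2 or 3, and each such fit also has fewer wells. The STAT3 transcript fell by 0.15 on the log2 scale (edgeR adjusted p = 0.0127, or 0.0597 without combination replicate 2).

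By list, cholesterol genes were mostly lower and antioxidant and heat shock genes mostly higher. The cholesterol list passed downward (24 of 24 fell, also when adjusted over the list alone, camera adjusted p = 1.64e-48). FDFT1 fell by 0.72 ± 0.054 and INSIG1 fell by 1.13 on the log2 scale. Of 20 NRF2 antioxidant genes 15 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 7.35e-14), with NQO1 at 0.62 ± 0.033 and HMOX1 at 1.28 ± 0.099. Of 15 heat shock genes 12 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 1.26e-12). DNAJB1 (0.78 ± 0.063), HSPH1 (0.47 ± 0.051) and HSPB1 (0.64 ± 0.082), which encode chaperones, were among them. Of 21 NF-kB and AP-1 genes 9 rose and 3 fell, or 10 and 4 when adjusted over the list alone (camera adjusted p = 1.72e-05). IL11 (2.40 ± 0.19), the collagenase gene MMP1 (1.48 ± 0.16) and RELB (0.79 ± 0.081) rose. Of 25 ATF4 stress genes 9 rose, among them ATF3 (1.45 ± 0.11) and the amino acid transporter gene SLC7A5 (0.79 ± 0.073), and 3 fell, among them TRIB3 (-0.32 ± 0.053, camera adjusted p = 0.00195). These 5 list calls held with an estimated correlation.

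Interferon-stimulated genes fell, 14 of 24 against 1 that rose, or 15 and 1 when adjusted over the list alone (camera adjusted p = 6.25e-11, adjusted p = 0.0951 with an estimated correlation). IFIT1 (-0.75 ± 0.068) and OASL (-0.98 ± 0.11) were among them. Of 25 replication genes 11 rose and 1 fell, or 12 and 1 when adjusted over the list alone (camera adjusted p = 0.00185, adjusted p = 0.334 with an estimated correlation). Of 19 hypoxia genes 2 rose and 8 fell (camera adjusted p = 0.0038, adjusted p = 0.255 with an estimated correlation). Of 15 luminal markers TFF1 rose and 7 fell, with a median of -0.188, a mean of 0.00325 and a test pointing down (camera adjusted p = 0.0238, adjusted p = 0.325 with an estimated correlation). Of 24 glucocorticoid-induced genes 5 rose and 10 fell, or 6 and 10 when adjusted over the list alone (camera adjusted p = 0.0514). Of 23 STAT3 targets 6 rose and 8 fell, or 7 and 8 when adjusted over the list alone (median -0.0442, mean 0.0686, test pointing up, camera adjusted p = 0.919). The mitotic genes (4 rose, 3 fell of 25, camera adjusted p = 0.808), ER chaperones (1 rose, 6 fell of 19, 0.058) and mesenchymal genes (9 rose, 4 fell of 18, or 9 and 5 when adjusted over the list alone, 0.197) did not pass. Several of these counts changed when a single library was left out (edgeR). Without combination replicate 2 the replication list had 7 rises, the STAT3 targets 5 falls, the glucocorticoid list 3 rises and 6 falls, the ER chaperones 2 falls and the mitotic list 0 rises and 4 falls. Without DEX replicate 2 the ER chaperones had 2 falls and the mitotic list 0 rises and 1 fall. The glucocorticoid list had 3 rises without DEX replicate 1 and 2 rises without DEX replicate 3 or combination replicate 1. The mitotic list had 1 rise without no-drug replicate 2, DEX replicate 1 or 3, SH4-54 replicate 2 or 3 or combination replicate 1, and 2 rises without no-drug replicate 3.

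**Figure D1:**
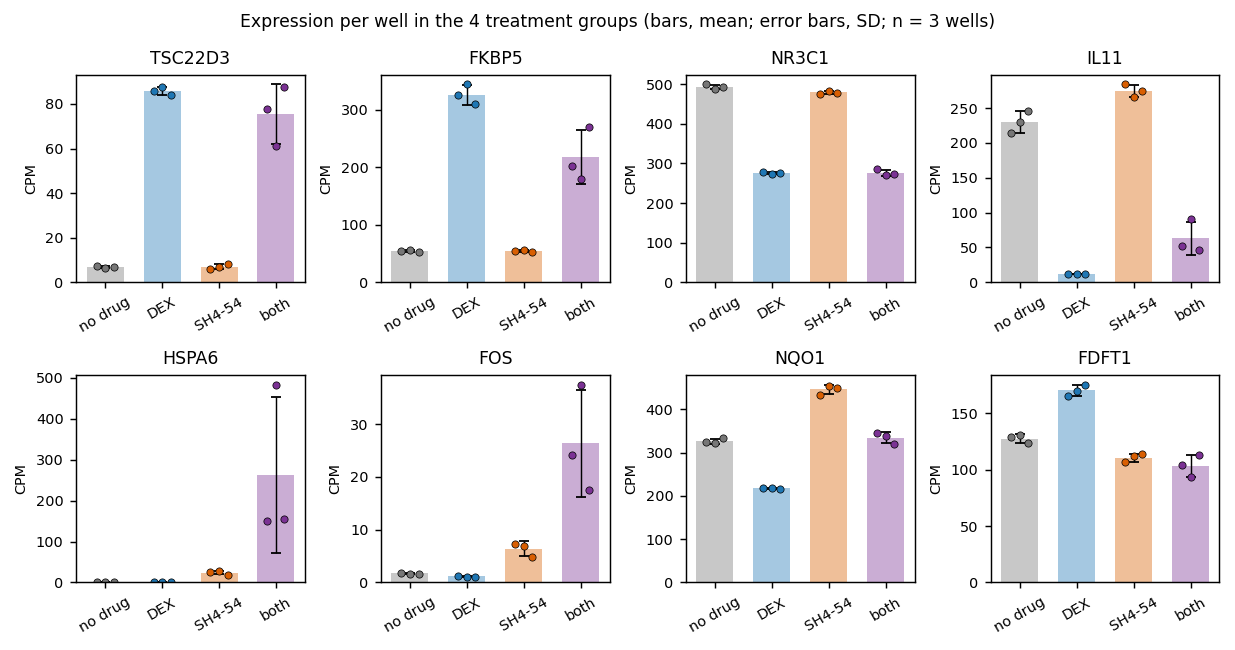
CPM of 8 genes in each well (points), with group means (bars) and SD (error bars), n = 3 wells per group, on linear axes starting at 0. TSC22D3 stood at 85.9 CPM with DEX and 75.5 CPM with both compounds and NR3C1 at 275 and 276 CPM, while IL11 stood at 11.9 and 63.2 CPM and HSPA6 at 0.394 and 263 CPM.

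The comparison of both compounds with SH4-54 alone gave the DEX effect in the presence of SH4-54. FKBP5 rose from 54.4 ± 2.3 to 218 ± 47.1 CPM and TSC22D3 from 7.01 ± 1.06 to 75.5 ± 13.3 CPM, and NR3C1 fell from 480 ± 3.9 to 276 ± 7.7 CPM. In all, 2854 genes rose and 2882 fell, 291 and 212 of them at least 2-fold. MAP2 (4.46 ± 0.34) and SLC7A7 (3.77 ± 0.24) rose, and ALOX15B, IP6K3 and DPEP1 reached 4.42 ± 3.02, 3.48 ± 2.2 and 3.36 ± 0.83 CPM. CLDN2 (-3.79 ± 0.20), LGR5 (-3.43 ± 0.13) and ASB2 (-2.52 ± 0.25) fell. HIST1H4K and HIST2H2BA, with wide spread between wells, were also called lower, and without SH4-54 replicate 2 the adjusted p of HIST2H2BA was 0.946 (edgeR).

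Glucocorticoid-induced genes (22 rose, 1 fell of 24, camera adjusted p = 4.47e-81) passed in that comparison, as did mitotic genes (24 of 25 fell, 5.5e-21), STAT3 targets (12 rose, 5 fell of 23, 0.00044) and mesenchymal genes (10 rose, 4 fell of 18, 1.66e-16). These held with an estimated correlation. When adjusted over the list alone, 1 mitotic gene rose and 5 mesenchymal genes fell. The ER chaperones passed with 12 up and 1 down of 19 (camera adjusted p = 0.0143, adjusted p = 0.272 with an estimated correlation). The luminal markers passed with 2 up and 6 down of 15, or 3 and 7 when adjusted over the list alone (camera adjusted p = 0.000545, adjusted p = 0.202 with an estimated correlation). The cholesterol list, with 5 up and 3 down of 24, or 4 and 3 when adjusted over the list alone, did not pass (camera adjusted p = 0.9). The NF-kB list had 8 up and 8 down of 21 (median -0.0085, mean 0.0286, 0.9) and the ATF4 list 5 up and 4 down of 25 (median -0.00727, mean 0.0165, 0.9). The NRF2 list had 5 up and 6 down of 20, or 5 and 7 when adjusted over the list alone (median 0.00415, mean 0.0452, test pointing down, 0.991). The replication list had 3 up and 4 down of 25 (median 0.00387, mean -0.00916, 0.9). The interferon list had 2 up and 9 down of 24, or 3 and 9 when adjusted over the list alone (0.0941). The heat shock list had 9 up and 3 down of 15 (0.089) and the hypoxia list 4 up and 6 down of 19 (0.313). Rises in the cholesterol list numbered 3 without no-drug replicate 2, any one SH4-54 replicate or combination replicate 3 and 8 without combination replicate 2, and its falls 5 without combination replicate 3 (edgeR). Rises in the replication list numbered 1 without SH4-54 replicate 2 or combination replicate 1, 0 without combination replicate 2 and 7 without combination replicate 3. The ATF4 list had 2 falls without SH4-54 replicate 3, and the luminal list 1 rise without SH4-54 replicate 1 or combination replicate 1.

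Against no drug, the combination changed 2992 genes upward and 3059 downward, 299 and 259 of them at least 2-fold. HSPA6, ALOX15B, ARC, IP6K3 and DPEP1 rose most among named genes. CLDN2 (-3.66 ± 0.20), LGR5 (-3.40 ± 0.13) and SPTSSB (-2.50 ± 0.16) fell, as did HIST1H4K and HIST2H2BA, the latter with an adjusted p of 0.921 without no-drug replicate 2 (edgeR). Glucocorticoid-induced genes (22 rose, 1 fell of 24, camera adjusted p = 2.98e-81), mitotic genes (24 of 25 fell, 2.19e-25), STAT3 targets (10 rose, 5 fell of 23, 8.36e-05) and mesenchymal genes (10 rose, 5 fell of 18, 7.59e-16) passed and held with an estimated correlation. Of 15 luminal markers 2 rose and 9 fell, or 2 and 10 when adjusted over the list alone (camera adjusted p = 2.8e-06, adjusted p = 0.0576 with an estimated correlation). Of 20 NRF2 genes 12 rose, FTH1 (1.21) among them, and 2 fell (camera adjusted p = 0.0021, adjusted p = 0.0576 with an estimated correlation). Of 24 interferon-stimulated genes 3 rose and 13 fell (camera adjusted p = 0.0021, adjusted p = 0.425 with an estimated correlation). Of 24 cholesterol genes 0 rose and 9 fell (camera adjusted p = 0.00829, adjusted p = 0.499 with an estimated correlation). Of 15 heat shock genes 8 rose and 3 fell, or 9 and 3 when adjusted over the list alone (camera adjusted p = 0.0167, adjusted p = 0.447 with an estimated correlation). The NF-kB (9 rose, 6 fell of 21, camera adjusted p = 0.0917), ER chaperone (10 rose, 1 fell of 19, or 10 and 2 when adjusted over the list alone, 0.0524) and hypoxia lists (4 rose, 7 fell of 19, median -0.0153, mean 0.136, 0.174) did not pass. Nor did the ATF4 (4 rose, 7 fell of 25, 0.936) and replication lists (3 rose, 4 fell of 25, 0.936). Without no-drug replicate 2 or 3 the ER chaperones had 6 rises and the replication list 2 falls, and without no-drug replicate 3 the luminal markers had 1 rise (edgeR). Without combination replicate 1 the mesenchymal list had 3 falls, and without combination replicate 3 the replication list had 7 rises and the interferon list 1.

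**Figure D2:**
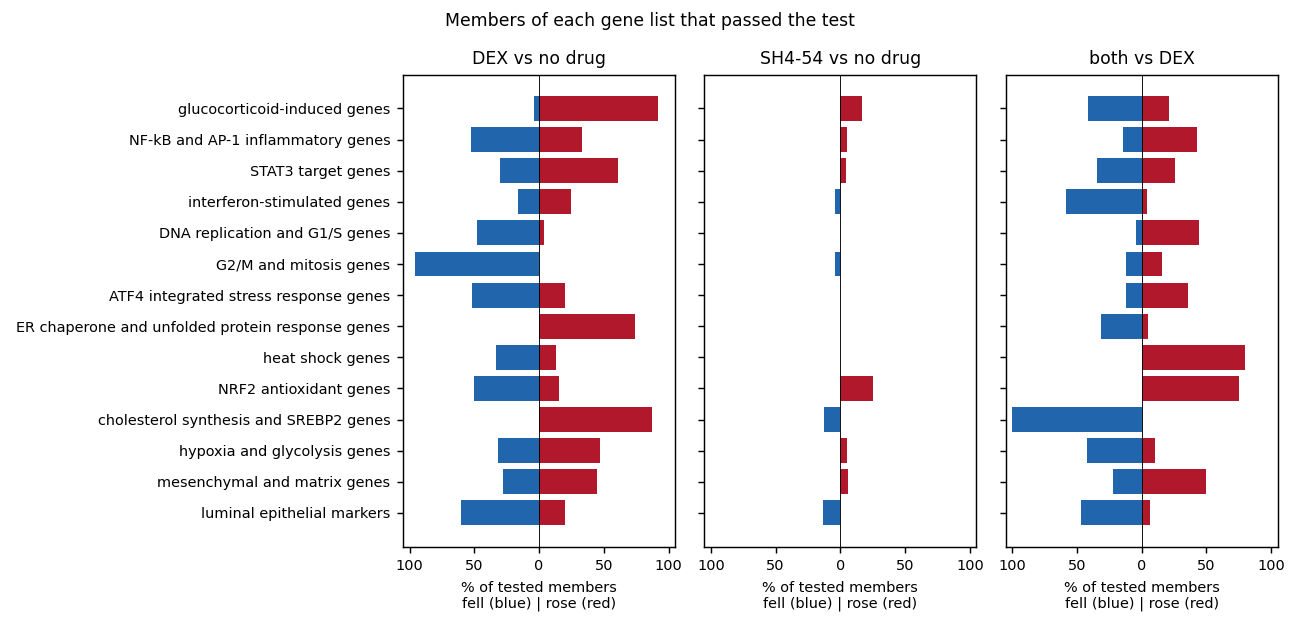
Share of the tested members of each fixed gene list that rose (red, to the right) or fell (blue, to the left) in 3 comparisons, in percent. With DEX alone 24 of 25 mitotic genes fell and 21 of 24 cholesterol genes rose, and with SH4-54 added to DEX 24 of 24 cholesterol genes fell.

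The interaction, the DEX effect with SH4-54 minus the DEX effect without it, asked which genes answered DEX differently when SH4-54 was present. DEX changed IL11 by -4.27 ± 0.19 on the log2 scale without SH4-54 and by -2.12 ± 0.16 with it, a difference of 2.14 ± 0.25 (edgeR adjusted p = 0.000575). The interaction was called for 553 genes, 346 with a positive and 207 with a negative value. Of 3104 genes that DEX raised, 171 had a negative and 11 a positive interaction, and of 3293 that it lowered, 285 had a positive and 6 a negative one. That choice of genes favours opposite signs, because the interaction subtracts the same DEX effect. Over genes chosen by the DEX effect averaged over both arms, a choice made after seeing the data and without that built-in link, 145 of 3794 risen genes had a negative and 40 a positive interaction, and 228 of 3942 fallen genes a positive and 28 a negative one. Positive values were largest among named genes for CCL26 (3.38 ± 0.35), the transcription factor genes SNAI1 (3.34 ± 0.59) and FOS (2.58 ± 0.45), and ASB2 (2.75 ± 0.55). RPL39 (2.51 ± 0.47, uncertain for its spread between wells), the luminal marker TFF1 (2.28) and IL11 came next. ANXA10 (2.02 ± 0.22), RELN (1.98 ± 0.18), COL17A1 (1.94 ± 0.30) and RASD1 (1.88 ± 0.24) followed. Negative values were largest for C3 (-1.53 ± 0.30), the protease inhibitor gene SLPI (-1.35 ± 0.29), SGPP2 (-1.15 ± 0.27), RPS6KA2 (-0.87 ± 0.19) and ANGPTL4 (-0.85 ± 0.11). SAA2 (-0.85 ± 0.22), ST8SIA4 (-0.84 ± 0.17), the desaturase gene SCD (-0.81 ± 0.17), PEG10 (-0.77 ± 0.16) and OASL (-0.76 ± 0.15) followed. The count changed with the library left out, and each such fit also has fewer wells. It was 365, 238 or 218 without no-drug replicate 1, 2 or 3, 258, 204 or 254 without DEX replicate 1, 2 or 3, 209 or 255 without SH4-54 replicate 2 or 3, and 296, 303 or 2046 without combination replicate 1, 2 or 3. The 2046 were 833 positive and 1213 negative genes, so the larger number of positive values did not hold there. It was 848 without a count filter, and DESeq2 split its 744 calls into 369 positive and 375 negative. Of 58 named genes with a called interaction, 33 kept the call whichever library was left out. Calls were lost for SGPP2 (edgeR adjusted p = 0.0943) and RPS6KA2 (0.071) and SCD (0.0662) without no-drug replicate 3, for SAA2 (0.132), SLPI (0.0659) and OASL (0.0518) without SH4-54 replicate 2, for ASB2 (0.067) without DEX replicate 2 and for ST8SIA4 (0.0501) without no-drug replicate 2.

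By list, of 24 cholesterol synthesis genes 16 had a negative interaction, or 23 when adjusted over the list alone (camera adjusted p = 9.51e-25, adjusted p = 0.0674 with an estimated correlation). FDFT1 (-0.51 ± 0.077), LSS (-0.49 ± 0.088), FDPS (-0.26 ± 0.047) and MSMO1 (-0.59 ± 0.11) were among them. The number was 9, 7 or 7 without no-drug replicate 1, 2 or 3, 8, 9 or 9 without DEX replicate 1, 2 or 3, 8 or 7 without SH4-54 replicate 2 or 3, 7 without combination replicate 1 and 22 without combination replicate 3. Of 25 ATF4 stress genes 5 were positive, including ATF3 (1.13 ± 0.16), SLC7A5 (0.57 ± 0.10) and SLC3A2 (0.43 ± 0.086), with 1 negative when adjusted over the list alone (camera adjusted p = 6.21e-05, held with an estimated correlation). Without no-drug replicate 2 or 3, DEX replicate 3, SH4-54 replicate 2 or combination replicate 1 there were 3. Without DEX replicate 2 there were 2, and SLC3A2 had an adjusted p of 0.0529 (edgeR). Negative ATF4 genes numbered up to 3 over left-out libraries. Of 15 heat shock genes 5 were positive, or 10 when adjusted over the list alone (camera adjusted p = 9.22e-09, adjusted p = 0.115 with an estimated correlation). HSPA1B (1.31 ± 0.25), DNAJB1 (0.63 ± 0.089), HSPH1 (0.45 ± 0.072) and HSPB1 (0.50 ± 0.12) were among them, with HSPB1 losing its call in 8 of 12 left-out fits (edgeR adjusted p = 0.0808 without DEX replicate 2). The number was 3 without no-drug replicate 2 or 3, any one DEX replicate, or SH4-54 replicate 2 or 3, and 8 without combination replicate 3. Of 24 glucocorticoid-induced genes 5 were negative and 1 positive, or 8 and 2 when adjusted over the list alone (camera adjusted p = 3.02e-05, adjusted p = 0.115 with an estimated correlation). The negative ones were ANGPTL4, MT1X (-0.70 ± 0.15), FKBP5 (-0.59 ± 0.15), RGS2 (-0.47 ± 0.080) and MT2A (-0.37 ± 0.059), with FKBP5 at an adjusted p of 0.104 without no-drug replicate 3 and MT1X at 0.0598 without SH4-54 replicate 3 (edgeR). There were 3 negative ones without no-drug replicate 1, DEX replicate 1 or 2 or SH4-54 replicate 3, and 9 without combination replicate 3. Of 24 interferon-stimulated genes 5 were negative, also when adjusted over the list alone (camera adjusted p = 1.79e-05, adjusted p = 0.237 with an estimated correlation). They included IFIT3 (-0.36 ± 0.064), IFIT1 (-0.45 ± 0.095) and STAT2 (-0.41 ± 0.094), and 1 was negative without SH4-54 replicate 2. The call of STAT2 was lost in 8 of 12 left-out fits (edgeR adjusted p = 0.0818 without no-drug replicate 3) and that of IFIT1 in 3 (0.0609 without SH4-54 replicate 2). The number was 2 without no-drug replicate 2 or DEX replicate 3, 3 without no-drug replicate 3, DEX replicate 1 or 2, SH4-54 replicate 3 or combination replicate 1, and 8 without combination replicate 3.

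Further lists passed for the interaction with the preset correlation alone. Their counts changed when a single library was left out. Without combination replicate 3 the hypoxia list had 9 negative and the mitotic list 9 positive genes. The replication list then had 8 positive and 1 negative, and the NRF2 list 5 positive and 3 negative. Of the lists below, the NF-kB list then had 5 of each sign, as did the mesenchymal list, the ER chaperones had 4 negative and the luminal markers 3 negative genes. The hypoxia list had 2 positive and 3 negative of 19, or 2 and 9 when adjusted over the list alone (camera adjusted p = 0.00012, adjusted p = 0.152 with an estimated correlation). The mitotic list had KIF20A (0.38) and BIRC5 (0.23) positive of 25, or 6 when adjusted over the list alone (camera adjusted p = 0.00222, adjusted p = 0.455 with an estimated correlation). The replication list had CDC25A (0.29) positive, or 3 when adjusted over the list alone (camera adjusted p = 0.00455, adjusted p = 0.455 with an estimated correlation). The NRF2 list had HMOX1 (0.67) positive, or 4 positive and 2 negative when adjusted over the list alone (camera adjusted p = 0.0416, adjusted p = 0.222 with an estimated correlation). Calls were lost for BIRC5 (edgeR adjusted p = 0.0785) and CDC25A (0.13) without no-drug replicate 3 and for HMOX1 (0.0586) without DEX replicate 2. The NF-kB list, with 5 positive, MMP1 (1.22 ± 0.21) among them, and 1 negative of 21, or 6 and 6 when adjusted over the list alone, did not pass (camera adjusted p = 0.062). It had 3 positive genes without any one of the no-drug or DEX replicates, or SH4-54 replicate 2 or 3. Nor did the STAT3 targets, with 2 positive and 2 negative of 23, or 5 and 6 when adjusted over the list alone (0.579), and with 5 and 7 without combination replicate 3. The mesenchymal list had 3 positive and 4 negative of 18, or 7 and 5 when adjusted over the list alone (0.644), with the matrix gene TNC at 0.70 ± 0.12, and its negative genes numbered 1 without no-drug replicate 2 or 3 or SH4-54 replicate 2. The ER chaperones had EDEM1 negative, or 3 when adjusted over the list alone (0.257), and its adjusted p was 0.126 without no-drug replicate 3 (edgeR). The luminal markers had TFF1 (2.28 ± 0.38) positive, and 2 negative when adjusted over the list alone (median -0.0306, mean 0.135, 0.972). The mitochondrial-genome list was not analysed here, because the table has no rows for its genes.

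**Figure D3:**
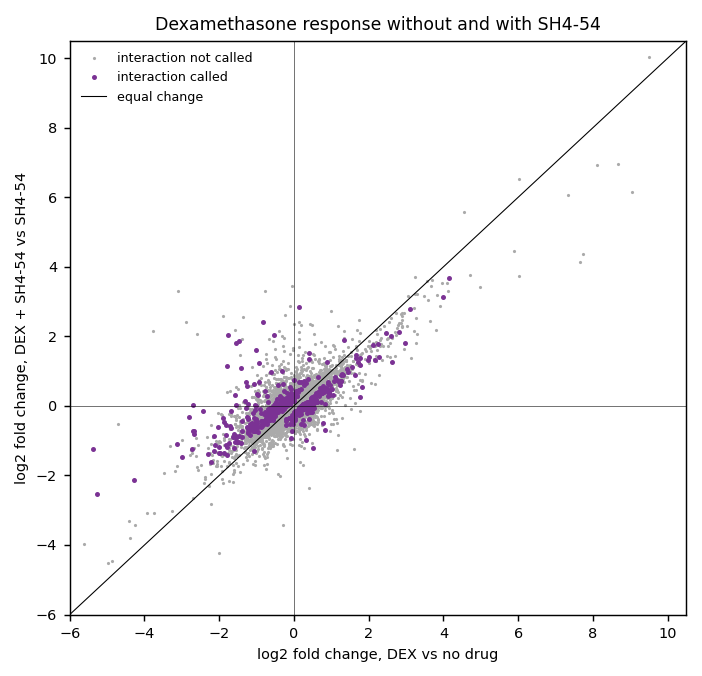
Log2 fold change of each tested gene with DEX against no drug (horizontal axis) and with both compounds against SH4-54 (vertical axis), with the 553 genes of called interaction in purple and a line at equal change. Of the genes raised by the DEX effect averaged over both arms, 145 called genes lie below the line and 40 above it, and of those lowered, 228 lie above it and 28 below it.

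Over the 6397 genes called with DEX alone, the median log2 fold change in the DEX direction with SH4-54 present was 0.702 times that without it (combination wells 0.704, 0.64 and 0.757, SD 0.058). Of these genes 92% moved in the same direction, and 4060 were called in both comparisons. The ratio depended on how genes were chosen. Chosen by the comparison of both compounds with SH4-54 it was 1.13, and chosen by the DEX effect averaged over both arms, a choice made after seeing the data, it was 0.866 (SD 0.0098). Both SDs vary the combination well alone and hold the other groups fixed, so they understate the uncertainty of the ratios. Across genes, which are not independent replicates, the DEX effects with and without SH4-54 had a Pearson correlation of 0.76 and the SH4-54 effects with and without DEX one of 0.416, in both cases with no library shared. Of 38 genes that rose with SH4-54 alone, 28 also rose when it was added to DEX (4.96 if independent), and of 47 that fell, 35 also fell (6.36 if independent). The 85 genes had a median absolute log2 fold change of 0.268 with SH4-54 alone and moved by 0.277 in the same direction with DEX. The 3770 genes called when SH4-54 was added to DEX had a median of 0.246 there. With SH4-54 alone they moved by 0.0515 in that direction, 74.2% of them with the same sign. Each choice of genes favours a larger value in the comparison that chose them and pulls the other towards 0. Neither pair of medians therefore measures how far DEX enlarges the SH4-54 effect.

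The effects of DEX and of SH4-54 alone share the no-drug libraries. Their correlation across genes was 0.12, or 0.22 and 0.191 without no-drug replicate 1 and 3, 0.327 with DESeq2 and 0.373 without a count filter, against 0.478 in simulated unchanged groups (edgeR, filtered). The simulated groups held no DEX effects, whose spread can lower a correlation, so 0.12 and 0.478 are not comparable. The covariance is not divided by that spread. It was 0.016, against 0.0157 ± 0.0012 in the simulation. They shared 14 risen genes (8.32 if independent) and 22 fallen genes (10.9 if independent). In opposite directions, 17 genes rose with DEX and fell with SH4-54 (10.3 if independent) and 12 fell with DEX and rose with SH4-54 (8.82 if independent).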

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

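The weighing of explanations in this part rests on tests that were all chosen after the result they bear on was seen, except the counts over other splits of the samples, which were fixed beforehand.

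The response to DEX differed with and without SH4-54 by a test of the difference itself for 553 genes. Among those named, the interaction log2 fold changes were positive for CCL26 (3.38), SNAI1 (3.34), ASB2 (2.75), FOS (2.58), RPL39 (2.51), TFF1 (2.28), IL11 (2.14), ANXA10 (2.02), RELN (1.98), COL17A1 (1.94), RASD1 (1.88), HSPA1B (1.31), MMP1 (1.22), ATF3 (1.13), JUN (1.01), TNC (0.70), DNAJB1 (0.63), SLC7A5 (0.57), HSPB1 (0.50), HSPH1 (0.45) and SLC3A2 (0.43). They were negative for C3 (-1.53), SLPI (-1.35), SGPP2 (-1.15), RPS6KA2 (-0.87), ANGPTL4 (-0.85), SAA2 (-0.85), ST8SIA4 (-0.84), SCD (-0.81), PEG10 (-0.77), OASL (-0.76), MT1X (-0.70), FKBP5 (-0.59), MSMO1 (-0.59), FDFT1 (-0.51), LSS (-0.49), RGS2 (-0.47), IFIT1 (-0.45), STAT2 (-0.41), MT2A (-0.37), IFIT3 (-0.36) and FDPS (-0.26). Of 100 random splits of the 12 libraries into 4 groups and the real one, 3 gave at least as many genes as the real 553, the real one included. This says nothing on chance: such splits put the DEX effect inside their groups, their dispersion was at least 3.51 times the real one (median 7.45 times), and 98 of them gave at most 1 gene. The highest other gave 3239 genes and the next 1637, several times the real count. Of the 6 libraries on the plus side of those contrasts, 5 and 4 had received DEX, against 1 and 2 on the minus side. A DEX effect may thus enter them, but other splits with 5 such libraries on the plus side gave 0 genes. The cause was not tested.

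Over the genes that DEX changed, DEX fold changes were smaller with SH4-54, though not over genes chosen by both compounds against SH4-54 (ratio 1.13). Choosing genes by DEX alone may not account for all of it, since genes chosen by the effect averaged over both arms still gave a ratio of 0.866. That is closer to 1 than 0.702, and its spread was taken over the combination wells alone. Less receptor transcript is argued against, since NR3C1 differed by 0.00466 ± 0.028 on the log2 scale between both compounds and DEX. One damping factor for every gene is argued against too, because 17.7% of the 683 genes changed at least 2-fold by DEX lay over 3 standard errors from the median share kept, against 1.9% in simulated data with 1 factor. That simulation gave every combination well the same factor, whereas the real wells kept 0.724, 0.604 and 0.747, so the percentages are not fully comparable. A STAT-dependent part of the glucocorticoid response and a general stress of the combination wells both stay open, since no sample separates them.

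SH4-54 changed 85 genes alone and 3770 when added to DEX. These counts do not test the difference between the 2 effects. The interaction does, since it equals the SH4-54 effect with DEX minus that without it, and it was called for 553 genes. Larger standard errors without DEX are argued against. With each comparison fitted on its own 6 libraries, the median over 3697 of the 3770 genes was 0.812 times that with DEX. It was at most 0.96 times whichever library was left out. Those own fits called 155 genes without and 2894 with DEX, a smaller gap than in the shared fit. Standard errors also leave out the adjusted p threshold, which admits more genes where more genes change. In the shared fit, 1862 and 5464 genes had an unadjusted edgeR p below 0.05. Power may thus account for part of the gap. A stronger exposure that scales every SH4-54 effect alike stays open. Of the 85 genes, 35.3% lay over 3 standard errors from the median ratio of 1.07. That percentage cannot decide, because no simulation gave the value for 1 common factor. The genes were also chosen by the effect without DEX, and the combination wells differed among themselves (HSPA6 at 150, 483 and 156 CPM). An exposure with a dose response that differs between genes stays open too. Counteraction of DEX may account for part of the calls: of 323 genes changed at least 2-fold by DEX and called in this comparison, 96% moved against DEX, although the DEX wells shared by both comparisons favour this by themselves (covariance of effects -0.0987, against -0.0171 in simulated unchanged groups). It leaves 1412 of the 3770 genes that DEX alone did not change by the test and 320 that moved with DEX.

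Within groups, 32 rows averaging at least 5 CPM differed at least 3-fold between wells, among them HIST1H4K (13.8 to 476 CPM), RPSA, ANXA2P1, PGAM4 and HSPA6. A library batch is argued against, since the rows' deviations had a median absolute correlation of 0.239, inside the 0.216 to 0.288 of 1000 shuffles. Reads shared with near-identical copies may account for part of them: 25.2% of the 50-base words of these rows (median of 30 rows found in the transcript set) occur in transcripts of another gene, against 0.457% at the 95th percentile of 10000 sets of rows of like level. By row the share ran from 1.81% (ACTA1) to 100% (HIST1H4K). HSPA6 was highest in combination replicate 2 (483 CPM), which was also the well farthest out on the second principal component (-31.4). No biological explanation was tested, and for HSPA6 the group difference (24 against 263 CPM) exceeds the spread between wells.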

How the results depend on the processing

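The choice of genes by the DEX effect of both arms was made after seeing the data. Counts of called genes for DEX, for both compounds against no drug and for both against SH4-54 stayed within 1.5 times under every alternative and left-out library (5526 to 6685, 5141 to 6233 and 4846 to 5729 over left-out libraries). For SH4-54 alone 85 became 180 with DESeq2, 176 without a filter (more genes tested), 155 with both groups alone, and 26 to 163 over left-out libraries. Both against DEX ranged from 2213 to 4633, and the interaction from 204 to 2046, with 848 unfiltered; the causes were not tested. The DEX response ratio of 0.702 became 1.13 with genes chosen by both against SH4-54 and 0.866 by both arms, and ranged from 0.671 to 0.729 over left-out libraries; the cause of the shift with the choice of genes is open. The correlation of DEX and SH4-54 effects, 0.12, became 0.327 with DESeq2, 0.373 unfiltered and 0.121 to 0.22 over left-out libraries; the cause was not tested. No named gene reversed. Of named gene values, 273 lost and 31 gained a call over left-out libraries, against 5204 that did neither; DESeq2 lost 6 and gained 16, and its size factors lost 1. Of list tests, 29 calls were lost with an estimated correlation and 55 kept their side of the threshold. Replicate numbers did not pair the libraries: no same-numbered pair of 18 correlated above 0.1 (-0.0975 to 0.0926) and 3 of 12 libraries matched their own number best. With the replicate block the 6 counts were 6162, 68, 5795, 3484, 5471 and 394, and the block lost 9 gene calls and 1 list call and gained 1 and 2. The simulated interaction recovered 13 of 50 changes of the smallest size simulated and 39 of 50 of 1.5-fold.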

Other observations

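The 5 groups of genes in this part, and their tests, were chosen after their values were seen, with no enrichment test, while the splits of the libraries were fixed beforehand. Of 14 tested immediate-early genes, 11 rose, 1 (KLF6) fell and 2 (IER3 and DUSP5) did not pass when SH4-54 was added to DEX, with a median log2 fold change of 2.01, and 3 rose with SH4-54 alone. JUN went from 42.6 ± 1.3 to 96.7 ± 19 CPM and EGR1 from 0.529 ± 0.13 to 3.75 ± 0.93 CPM.

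Of 6 metallothionein genes, which encode metal-binding proteins, 6 rose with DEX (median 2.64), MT1E from 82.9 ± 2.4 to 714 ± 44 CPM. When SH4-54 was added to DEX, MT1X fell (89 to 61.7 CPM, edgeR adjusted p = 0.00123), and MT1E stood at 665 ± 57 CPM. The interaction was called negative for MT1X, MT2A and MT1E. Of 7 acute-phase genes 7 rose with DEX, and 6 fell and 1 (C1S) did not pass when SH4-54 was added, SAA1 going from 14.8 ± 1.7 to 135 ± 1.7 and then 86.8 ± 18 CPM. Of 10 fatty acid synthesis genes 9 fell when SH4-54 was added to DEX, among them SCD (422 ± 17 to 192 ± 50 CPM), FADS2 (255 ± 6.4 to 177 ± 8.9 CPM) and ACSS2 (85.8 ± 2.0 to 51.5 ± 7.4 CPM). Of 9 replication-dependent histone genes 6 fell and 0 rose with DEX (median -0.17), and 1 fell when SH4-54 was added.

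More genes were detected in the combination wells: 18392 to 18995 had at least 1 count, against 17297 to 18056 in the other wells. Thinned to the smallest total, 25577213 reads, the ranges were 18287 to 18859 with both compounds, 17623 to 17860 with SH4-54, 17438 to 17528 without drug and 17277 to 17354 with DEX.

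Splits of 6 libraries 3 against 3 number 10, too few for a share under 0.05. Fitted on the 6 libraries, the real split was the 1 that gave its count: 6876 genes for DEX (highest other 0), 155 for SH4-54 (4), 5520 for both against no drug (0), 2894 for both against DEX (1) and 4784 for both against SH4-54 (0). This says nothing on chance either. Every other split mixes wells of both groups, so a treatment effect widens the spread inside its groups and lowers its count.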
